A study of Homo sapiens with 64 samples.

How the data were processed

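The series holds 64 human cell line libraries. HEK293T is a line from embryonic kidney that carries the large T antigen of simian virus, and C4-2 is an androgen-independent prostate cancer line. FBL (fibrillarin) is the methyltransferase of the box C/D snoRNP, the small nucleolar ribonucleoprotein that 2′-O-methylates ribosomal RNA, and NOP56 is a scaffold protein of the same particle. Both were lowered with small interfering RNAs (siRNAs), siFBL and siNOP56, against a control siRNA, siCTRL. The sample labels name siNOP56, while the series design names shNOP56 in its place; the labels were followed.

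A HEK293T time course held 24 RNA-seq libraries (siCTRL, siFBL and siNOP56 at 0, 6, 12 and 24 h, 2 each), and a C4-2 time course held 16 (siCTRL and siFBL at 0, 3, 6 and 12 h, 2 each). The labels give the purpose of the hours as mRNA half-life; how transcription was blocked is not given in the sources used here. RNA immunoprecipitation (RIP) with an antibody against FBL gave 2 RIP and 2 input libraries from C4-2 cells with siCTRL. SLAM-seq, in which thiol-labelled uridine taken up by new RNA is read as T>C conversions, gave 16 libraries of C4-2 cells (siCTRL and siFBL at 0, 6, 12 and 24 h, 2 each). Per the labels' protocols, cells were labelled with 100 µM 4-thiouridine for 24 h and then chased with an excess of uridine, and 3′ end libraries were made. The remaining 4 libraries, nanopore reads of C4-2 RNA, were not analysed here.

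The RIP and time-course values that the authors deposited are whole-number read counts per gene symbol for each library, with no normalisation seen in the values. TopHat2 2.1.1 and HOMER are named per the submitters' processing notes, with no role stated; the aligner and the counting tool of each table are not given in the sources used here. hg38, GRCh38.p13 and hg19 are named for these samples without a role, so no coordinates are printed for them. Whether counting used strand is not stated, so reads of overlapping and antisense genes, and of near-identical genes such as histone, snoRNA and ribosomal protein copies, cannot be told apart in these counts.

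The SLAM-seq values that the authors deposited are read counts, counts of reads with T>C conversions, counts of sequenced T positions and counts of T>C conversions per annotated 3′ UTR interval. They were made with slamdunk 0.4.3, per the file headers, after Trim Galore, per the submitters' processing notes, on hg38. Its deposited CPM column was treated as a score, used only to recover the number of mapped reads, because a read is counted in every interval it overlaps, so that the column sums to more than a CPM column can. The 117417 intervals carry 31796 gene names, and 18327 of them repeat an earlier line with the same coordinates and name. Each gene is represented by its interval with the most reads over the 16 libraries.

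The total counts per library were 22.9 to 33.3 mega (M) in RIP, 79 to 106.1 M in C4-2 and 16 to 19.9 M in HEK293T. SLAM-seq libraries had 14.3 to 60.3 M mapped reads. No molecular identifiers are stated, so precision that follows from counts covers counting error only.

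Groups follow the labels. The C4-2 columns could be matched to groups but not to single samples, so their libraries are called A and B, in the order of the numbers in the column names. In SLAM-seq the labelled hour differs from the hour in the file header in 12 of 16 libraries, while the siRNA is the same in both for each of the 16. A comparison over the labelled hours was to be reported only if the share of T>C reads at labelled 0 h lay above that at labelled 24 h in each replicate of both siRNAs. That check failed, so no SLAM-seq decay comparison is given. Nothing in the labels states that replicates are separate cultures, so each p-value measures the spread between samples, which may be technical.

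Counts were fitted with edgeR 4.0.16 (trimmed mean of M-values normalisation, its default filter on low counts, quasi-likelihood test) in R 4.3.3, and Benjamini-Hochberg adjusted p-values below 0.05 were called. Contrasts at 0 h used every library of the time course with 1 mean per siRNA and hour. Their p-values treat libraries of different hours as independent, although replicates deviated alike at each hour within siFBL and siNOP56. Decay was compared as the interaction of siRNA and hour, in log2 per hour relative to the other mRNAs of the library. A global change in decay therefore cannot be seen, and a positive slope means slower loss than the average mRNA. The contrast of siFBL with siCTRL in C4-2 was compared with that in HEK293T in 1 model of both time courses. SLAM-seq total reads were fitted with siRNA and labelled hour, and the share of T>C reads with these and a library term.

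Named genes follow a rule set before the data were examined, as were the comparisons, the gene lists, the named-gene rule and all alternatives not said to be added later. FBL and NOP56 are given always. Called genes with a mean of at least 5 CPM (counts scaled to a common library size) and no overlap between the groups' libraries supply the 6 highest and 6 lowest changes. Each gene list supplies up to 2 called members with the smallest p. Where fewer than 4 genes are called, the 4 with the smallest p are named. Genes with only a clone name or an identifier, XIST and Y-linked genes are passed over.

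The gene lists include the box C/D snoRNP core, snoRNP assembly factors, the H/ACA snoRNP core, ribosome biogenesis factors, cytosolic ribosomal proteins, snoRNA host genes, p53 targets, the integrated stress response, the unfolded protein response, G2/M genes, S phase and E2F targets, the interferon response, cholesterol biosynthesis, glycolysis, the nuclear-encoded respiratory chain, short-lived mRNAs, m6A and other RNA methylation factors, mRNA decay machinery, reported nonsense-mediated decay targets, replication-dependent histones, and markers of C4-2, HEK293T, fibroblasts, leukocytes and neuroendocrine cells. They were tested with camera (limma 3.58.1) on edgeR z-scores with a preset correlation of 0.01, adjusted over the lists of a comparison. Each list was also tested with an estimated correlation. A list of mitochondrially encoded mRNAs matched 0 gene names in each of the 4 assays and was not tested. RNAs enriched in RIP (adjusted p below 0.05 and log2 above 1) formed a further list.

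Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, scaling to ribosomal protein mRNAs, leaving out each library, a replicate block where replicates are numbered, 0 h libraries alone, hour as a factor, and time courses without the last hour. A replicate block within each siRNA, a block from the numbers in the C4-2 column names, SLAM-seq reads summed over distinct intervals, SLAM-seq without 2 libraries and SLAM-seq total reads with the hour of the file header were added after seeing the data. Gene lengths came from an annotation table matched by symbol, and random gene lists were matched on mean expression.

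The fits were tested on simulated counts with 200 genes changed 2-fold or 4-fold. Simulated libraries were drawn independently of each other, with 1 dispersion per gene for all groups of a fit. In the time courses replicates deviated alike at each hour within siFBL and siNOP56, so the recovered and false shares may not hold there. At 2-fold and 4-fold, the share recovered was 90% and 98% for RIP, 19% and 53% for C4-2 at 0 h, 34% and 86% for siFBL and 37% and 76% for siNOP56 in HEK293T at 0 h. It was 31% and 81% for siFBL against siNOP56 at 0 h, 8% and 47% for the comparison of cell lines, and 48% and 64% for SLAM-seq total reads. Slopes that give these folds by the last hour were recovered in 2% and 30% of genes in C4-2, and in HEK293T in 3% and 50% for siFBL, 0% and 39% for siNOP56 and 1% and 50% for their difference. The test of the T>C share, which held the labelled hour, recovered 0% at both folds with the real spread between libraries. It recovered 73% and 81% when conversion rates were made equal and the dispersion was set to 0.01. With the labelled hour it could thus not have seen such changes in these libraries. The share was not fitted with the hour of the file header. Of all calls on simulated counts, the share that was false was 8.7% for RIP, 5.3% at 0 h and 8.6% for slopes in C4-2, 8.1% for siNOP56 at 0 h, 5.4% for siFBL slopes and 7.3% for slopes of siFBL against siNOP56 in HEK293T, 11.5% for the T>C share with equal rates, and 0% to 4.8% otherwise. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.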

Results

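The study measured mRNA levels in human cells in which the box C/D snoRNP was lowered, and asked whether FBL binds mRNAs and alters their stability. Of its 64 libraries, 60 are analysed here. HEK293T cells gave 24 time-course libraries of 16 to 19.9 mega (M) counts, and C4-2 cells 16 of 79 to 106.1 M. RNA immunoprecipitation (RIP) from C4-2 cells gave 4 libraries of 22.9 to 33.3 M counts. SLAM-seq of C4-2 cells gave 16 libraries of 14.3 to 60.3 M mapped reads. Values per group are means ± SD of 2 libraries in CPM unless stated. CPM are counts scaled to a common library size, for these means with trimmed mean of M-values factors. Changes are log2 values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

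Each knockdown lowered its target. In C4-2 cells at 0 h, FBL fell from 285.2 ± 27.9 CPM with siCTRL to 3.19 ± 0.614 with siFBL (n = 2 each), which is 89.3-fold lower (log2 −6.48, SE 0.584, edgeR adjusted p = 4.23e-06). At 12 h the siFBL libraries held 1.17 ± 0.811 CPM of FBL against 381.3 ± 9.19 with siCTRL. In HEK293T cells at 0 h, FBL fell from 317.4 ± 6.29 to 16.6 ± 1.53 CPM with siFBL (19.1-fold lower, edgeR adjusted p = 1.21e-05), and stayed at 11 ± 5.37 CPM at 24 h. NOP56 fell less far, from 204.8 ± 1.34 to 84.2 ± 11 CPM with siNOP56 (2.43-fold lower, edgeR adjusted p = 0.0287). FBL was at 356 ± 21.4 CPM with siNOP56 at 0 h, a difference from siCTRL that was not called (edgeR adjusted p = 0.875). NOP56 stood at 356.6 ± 4.03 CPM with siFBL in HEK293T (log2 0.80, edgeR adjusted p = 0.067) and at 160.2 ± 15.1 against 212 ± 20.4 CPM in C4-2 (log2 −0.41, edgeR adjusted p = 0.207), neither of them called. In SLAM-seq, the FBL interval (hg38, chromosome 19, 39834458 to 39834537, minus strand) held 2 to 54 reads in each siCTRL library and 0 to 2 in each siFBL library. NOP56 (hg38, chromosome 20, 2658295 to 2658393, plus strand) was not called there (log2 0.07, edgeR adjusted p = 0.966). Its sign rests on 2 siFBL libraries at 57.3 and 58.1 CPM, with header hour 24, for which siCTRL lies at 14.4 and 14.8; without them it was −0.08.

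**Figure D1:**
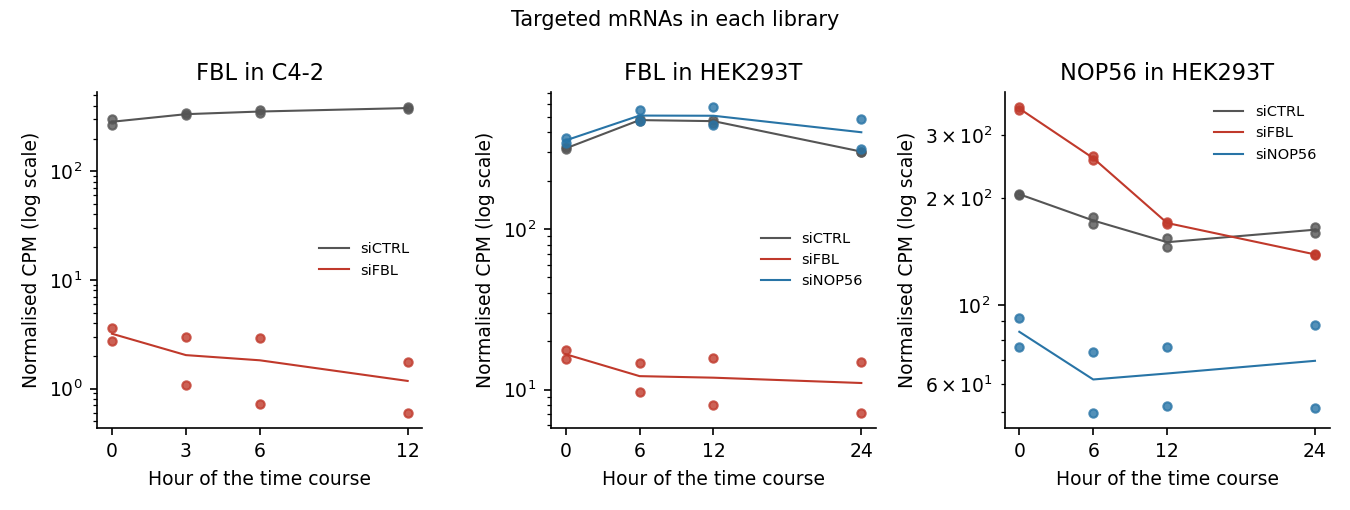
FBL and NOP56 levels in CPM on a log axis (vertical) by hour of the time course (horizontal) for each siRNA in C4-2 and HEK293T cells; points are libraries and lines join group means. FBL in C4-2 cells at 0 h lies at 285.2 CPM with siCTRL and 3.19 CPM with siFBL.

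The RIP comparison asks which RNAs are enriched over input with an antibody against FBL. No control antibody and no RIP after siFBL are among the samples, so enrichment alone does not show binding by FBL. FBL is the methyltransferase of the box C/D snoRNP, whose guide RNAs are the SNORD snoRNAs and, in Cajal bodies, several SCARNAs, so these RNAs are its known partners. SNORA snoRNAs guide pseudouridylation in H/ACA particles, which lack FBL. In siCTRL cells, RIP and input differed in 12406 of 14967 RNAs, 5967 higher and 6439 lower in RIP, and 3303 lay above log2 1. The largest enrichments that the rule names were SCARNA7 (34.1 ± 9.49 CPM in RIP against 0.297 ± 0.0185 in input, 113-fold, log2 6.82), SCARNA9 (6.52), SCARNA9L (6.23), SCARNA21 (6.19), SNORD116-18 (6.09) and SNORD116-14 (5.85). All 102 SNORD RNAs tested were enriched (median log2 4.26), as were all 10 SCARNAs (median 5.66), while 18 of 24 SNORA RNAs were depleted and 2 enriched (median −1.37). These classes were counted after the values were seen. Reads of a snoRNA and of the host intron around it cannot be told apart in these counts.

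Among mRNAs, the centromere proteins CENPF (log2 4.72) and CENPE (3.58), the decay kinase SMG1 (3.72) and the pre-rRNA processing factors UTP20 (3.62) and HEATR1 (3.05) were enriched, as were the exonuclease XRN1 (2.69), the decay factor UPF2 (2.57), the m6A writer subunit KIAA1429 (2.55), the m6A reader YTHDF2 (2.12), PARP14 (3.01) and the protease TMPRSS2 (2.02). NOP56 mRNA rose from 101.2 ± 2.5 to 360 ± 23 CPM (3.56-fold, edgeR adjusted p = 1.73e-21), and FBL mRNA from 63.9 ± 1.15 to 80.5 ± 0.665 (1.26-fold, edgeR adjusted p = 1.82e-05). The normalisation factors behind these CPM were 1.388 and 1.385 in input against 0.727 and 0.716 in RIP. Raw FBL counts were 2086 and 1999 in input and 1945 and 1906 in the larger RIP libraries. Enrichment and depletion are therefore relative to this reference level, and the direction for FBL mRNA depends on it. The lowest were RPL39 (log2 −4.55, 23.4-fold lower), TMSB15A (−4.43), TMEM256 (−4.36), NDUFA4 (−4.31), COX7A2 (−4.21) and RPA3 (−4.17). Histone HIST1H4C (−4.07), the host transcript SNHG3 (−2.39) and the kallikrein KLK4 (−2.70) were also depleted, while the host transcript SNHG1 (2.36) was enriched.

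By list, 59 of 77 ribosomal protein mRNAs were depleted and 10 enriched (median −0.78, camera adjusted p = 8.41e-11), as were 31 and 8 of 40 respiratory chain mRNAs (median −1.90, camera adjusted p = 5.39e-10), 23 and 2 of 27 histones (median −1.51, camera adjusted p = 2.37e-08) and 16 and 3 of 21 snoRNA hosts (median −1.54, camera adjusted p = 0.00254). Nonsense-mediated decay targets (13 of 19 enriched and 6 depleted, camera adjusted p = 0.0372) and glycolysis (16 of 20 enriched and 4 depleted, camera adjusted p = 0.0395) went the other way. Adjusted over the list alone, these counts were the same. None of the 6 lists passed with an estimated correlation: adjusted p = 0.46 with an estimated correlation for the 4 depleted lists, 0.519 for decay targets and 0.9 for glycolysis. Ribosome biogenesis factors (30 of 46 enriched, 13 depleted, camera adjusted p = 0.0834), G2/M genes (21 and 11 of 33), S phase genes (22 and 12 of 35), decay machinery (26 and 24 of 52) and RNA methylation factors (14 and 12 of 29) were mixed.

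RIP enrichment rose with transcript length. A length could be given to 13993 of the 14967 RNAs (93.5%). Across the 12866 protein-coding ones, Spearman's rho between length and log2 enrichment was 0.466; this is a relation across genes, which are not independent replicates, and it was examined after the values were seen. The median log2 was −0.94 among the 3216 shortest transcripts (median length 1792.5 nt, 627 enriched and 2129 depleted) and 0.83 among the 3217 longest (median 7167 nt, 2208 enriched and 599 depleted). Of 241 lincRNAs, 141 were depleted and 28 enriched.

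**Figure D2:**
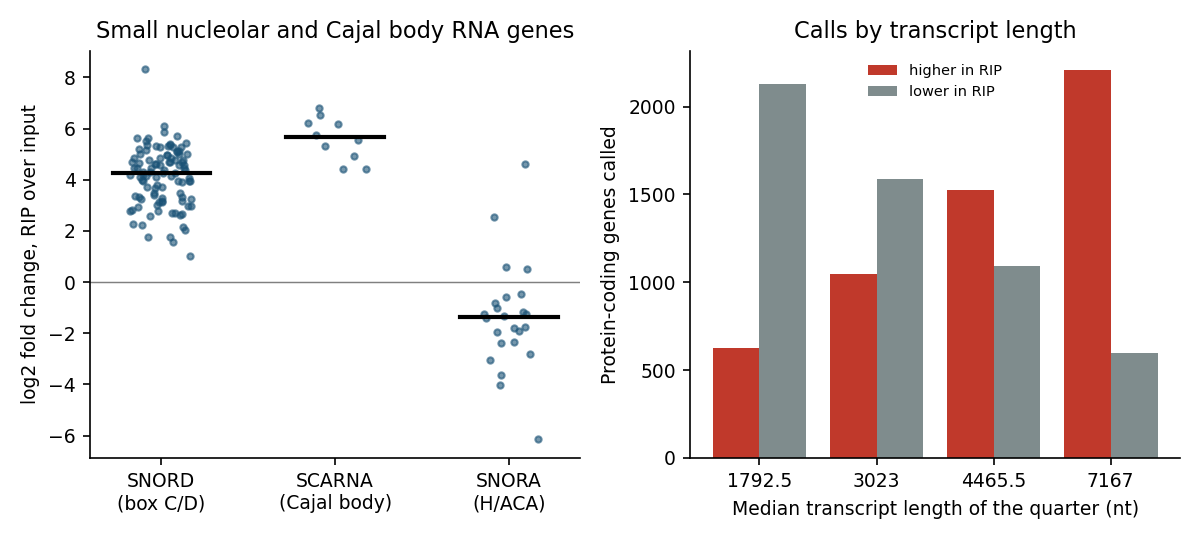
RIP over input in C4-2 cells, as log2 for each SNORD, SCARNA and SNORA RNA, and by 4 bins of transcript length in nt for protein-coding genes. Medians are 4.26 for SNORD, 5.66 for SCARNA and −1.37 for SNORA RNAs.

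At 0 h of the C4-2 time course, siFBL was compared with siCTRL in these prostate cancer cells. The largest response was in the genes of DNA replication and mitosis, which fell together. p53 target genes rose. Genes for making ribosomes lay lower by smaller amounts, a shift that did not pass with an estimated correlation. At 0 h, 1988 of 23437 genes changed with siFBL, 377 up and 1611 down (4015 by DESeq2, 633 to 3051 without single libraries).

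All 33 G2/M genes fell (median log2 −2.12) and so did 34 of 35 S phase and E2F targets (median −1.76), with the same counts adjusted over the list alone. The camera adjusted p was 7.81e-78 for G2/M and 2.7e-83 for S phase genes, and 0.0301 and 0.0136 with an estimated correlation. The proliferation antigen MKI67 fell from 249 ± 17.3 to 40.9 ± 9.81 CPM (log2 −2.61). The spindle protein ASPM (−2.63), the kinesin KIF14 (−2.60), the repressor E2F8 (−2.58) and the checkpoint adaptor CLSPN (−2.58) fell most, beside FBL itself. The helicase subunits MCM7 (589.3 ± 36.4 to 171.6 ± 3.55 CPM, −1.78) and MCM4 (−2.05), the cyclin kinase partner CKS1B (−1.93) and CDCA3 (−1.98) fell with them. The exception among S phase genes was CCNE1, at log2 0.06 and not called, which was picked out after the values were seen.

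Of 28 p53 targets, 19 rose and 0 fell (24 up adjusted over the list alone; median 1.25, camera adjusted p = 1.61e-26, 0.0333 with an estimated correlation); none was lower at an unadjusted p under 0.05 in edgeR (0) or was called lower by DESeq2 (0). The cyclin kinase inhibitor CDKN1A rose 20.5-fold (log2 4.36, edgeR adjusted p = 0.000118), from 129.2 ± 4.39 to 2654 ± 1860 CPM, the SD showing how far apart the siFBL libraries lay. The cytokine GDF15 rose from 1199 ± 15.4 to 4574 ± 794 CPM (1.93), TP53I3 (3.50) and PHLDA3 (1.77) rose, and so did the stress gene GADD45A (2.31). Outside the lists, the lipase CEL (4.95), the sulfatase SULF2 (0.501 ± 0.0387 to 13.1 ± 6.93 CPM, 4.70), FAXDC2 (3.62) and SERPINB5 (2.81) rose most. In the interferon list, 8 of 38 genes rose and 2 fell (10 and 2 adjusted over the list alone; median 0.40, camera adjusted p = 0.000535, 0.0333 with an estimated correlation), with IFI6 up (1.81) and the synthetase OAS3 down (−1.59).

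Genes for ribosome production moved down by less. Of 46 biogenesis factors, 11 fell and 0 rose (20 down adjusted over the list alone; median −0.43, 45 of 46 below 0; camera adjusted p = 7.89e-08), among them the polymerase I factor TCOF1 (−1.57) and MRTO4 (−0.77). The remaining lists with lower medians were snoRNA hosts (6 of 21 down, limma camera adjusted p = 2.53e-05; SNHG1 −1.62, CWF19L1 −1.06), ribosomal proteins (7 of 78 down, median −0.20, adjusted p = 0.000418; RPS9 −0.73, RPL10A −0.57), snoRNP assembly factors (3 of 11, adjusted p = 0.0142; PIH1D1 −0.78, NUFIP1 −0.78), mRNA decay machinery (17 of 52, adjusted p = 8.1e-07; LSM2 −1.08, SMG1 −0.80), decay targets (9 of 20 down, 1 up, adjusted p = 7.72e-05), the unfolded protein response (6 of 18, adjusted p = 0.000402; MANF −0.68, PDIA4 −0.56), the integrated stress response (6 of 25 down, 2 up, adjusted p = 0.0256; PHGDH −0.71, ATF4 −0.65), cholesterol synthesis (6 of 24 down, 1 up, adjusted p = 0.00591; EBP −1.07, FDPS −0.83) and glycolysis (5 of 20, adjusted p = 0.0122; HK2 −0.84, PFKFB3 −0.83). RNA methylation factors also passed with a median of −0.34 (camera adjusted p = 0.00702), although edgeR called 0 of 30, against 11 lower and 0 higher at an unadjusted p under 0.05 and 9 lower and 0 higher by DESeq2. With an estimated correlation none of these 11 lists passed (adjusted p from 0.295 to 0.552 with an estimated correlation).

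The signs and calls of these smaller shifts depend on the reference level. It moves all genes alike, so it does not bear on the comparison of a list with the other genes that camera makes. Scaling to ribosomal protein mRNAs raised the median of all genes from 0.041 to 0.26, and 3 biogenesis factors were then down (median −0.22). Under that scaling the medians of ribosomal proteins (0.02, by construction), cholesterol synthesis (0.02), the respiratory chain (0.19) and C4-2 markers (0.14) changed sign. G2/M, S phase, p53 and interferon lists kept their direction.

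Lists that did not pass in C4-2 cells included the H/ACA core (2 of 6 down, DKC1 −0.57 and NAF1 −0.75, camera adjusted p = 0.0724), histones (2 of 28 down, HIST1H2AL −2.41 and HIST1H2BJ −1.81, 0.0611), C4-2 markers (1 of 20 up, TMPRSS2, and 3 down, with SPDEF at −0.61, 0.486), short-lived mRNAs (3 of 42 up and 1 down, 0.273), the respiratory chain (median −0.03, 0.724), leukocyte markers (median 0.12, 0.53) and neuroendocrine markers (median 0.78, 0.0892). DKC1 and NAF1 lost their call in 11 of 22 alternatives and HIST1H2AL in 12. HEK293T markers had a positive median (0.62) and mean (0.26) but a downward test (0.519), with NES (−1.48) and HOXA10 (−1.25) down. Fibroblast markers passed upward (median 0.998, camera adjusted p = 0.0302) but not with an estimated correlation (adjusted p = 0.295 with an estimated correlation). The box C/D core passed (median −0.41, mean −1.87, camera adjusted p = 0.000987; adjusted p = 0.0604 with an estimated correlation), and its called gene was FBL.

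Later in the C4-2 time course, 2794 genes were called at 3 h, 2122 at 6 h and 3144 at 12 h. RNAs enriched in RIP lay lower at 0 h: of 3274 tested, 480 fell and 47 rose (median −0.29), which passed limma camera at 0.05 with the fixed correlation and did not pass with an estimated one (p = 0.0972 with an estimated correlation).

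The C4-2 time course asks whether mRNAs are lost at another rate without FBL. mRNAs of transcription factors and cytokine-response genes turn over within hours, while those of the ribosome and the respiratory chain are long-lived. Both patterns were seen here with either siRNA. Few differences between siRNAs in these rates were called, by a test that recovered 2% of simulated 2-fold differences.

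With siCTRL, 34 of 42 short-lived mRNAs fell relative to the library (median −0.34 log2 per hour), and with siFBL 32 of 42 (median −0.43). The kinase PIM1 changed by −0.29 per hour with siCTRL and −0.46 with siFBL, and JUND by −0.32 and −0.43. The ribosomal protein mRNAs rose in relative terms (76 of 78 with siCTRL, 75 of 78 with siFBL), as did respiratory chain mRNAs (39 and 40 of 40), with NDUFA4 at 0.11 per hour for both siRNAs. In the test of the difference between the siRNAs, edgeR called 1 of 23437 genes, with 1117 at an unadjusted p under 0.05, and DESeq2 called 24. The called gene was the decapping coactivator PNRC2, which was lost faster with siFBL (−0.17 per hour, SE 0.025, edgeR adjusted p = 0.0482), a call that ended in 20 of 24 alternatives. Next were HDAC7 (−0.10, edgeR adjusted p = 0.177), LRRC47 (0.07) and the GTP-binding protein GTPBP2 (−0.20, edgeR adjusted p = 0.248), none of them called. G2/M genes had a lower slope with siFBL (median −0.03 per hour, 28 of 33 lower, camera adjusted p = 0.000294), which was lost with an estimated correlation (adjusted p = 0.994 with an estimated correlation). Short-lived mRNAs did not pass (29 of 42 lower, camera adjusted p = 0.265). RIP-enriched RNAs did not pass limma camera at 0.05 for the slope (median 0.00 per hour), and the 500 with the highest RIP fold passed upward with the fixed correlation (median 0.01 per hour) and did not with an estimated one (p = 0.228 with an estimated correlation). FBL itself had a slope difference of −0.15 per hour (edgeR adjusted p = 0.902) and NOP56 of −0.04 (edgeR adjusted p = 1).

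FBL knockdown in HEK293T cells changed fewer genes than in C4-2 cells. The stress programs of amino acid supply and of the endoplasmic reticulum fell. p53 targets rose. No cell cycle gene was called. At 0 h, 260 of 14939 genes changed, 139 up and 121 down; the count was 778 by DESeq2, 861 with a replicate block, 1 with the 0 h libraries alone and 11 to 363 without single libraries.

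The glucose-regulated TXNIP rose 3.5-fold (19.9 ± 1.6 to 69.5 ± 5.26 CPM, log2 1.81, edgeR adjusted p = 0.00354), and CIDECP (1.83), NOXO1 (1.81), the tRNA methyltransferase subunit TRMT61A (1.65), SEMA3C (1.49) and COX19 (1.47) were the other largest rises. TRMT61A lost its call in 18 of 30 alternatives, CIDECP in 16, NOXO1 in 14, SEMA3C in 5, COX19 in 4 and TXNIP in 3. The box C/D snoRNA SNORD17 fell (5.08 ± 0.787 to 1.17 ± 0.411 CPM, log2 −2.12, edgeR adjusted p = 0.000814). C1orf95 (−1.96), the cystine transporter SLC7A11 (−1.78), the ribosomal protein paralog RPL22L1 (−1.71) and SULT1A1 (−1.70) were the other largest falls beside FBL. RPL22L1 lost its call in 11 of 30 alternatives and SULT1A1 in 8. The core protein NOP58 rose (0.69).

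p53 targets rose as a list (5 of 28 up and 0 down, 10 up adjusted over the list alone; median 0.51, camera adjusted p = 2.11e-09, 0.0018 with an estimated correlation), led by the nuclease AEN (66.3 ± 1.46 to 138.7 ± 10.7 CPM, log2 1.07) and the death receptor TNFRSF10B (0.93). The integrated stress response fell (5 of 25 down; 2 up and 8 down adjusted over the list alone; median −0.28, camera adjusted p = 0.000179, 0.00776 with an estimated correlation), led by the asparagine synthetase ASNS (100.9 ± 1.9 to 39.2 ± 6.77 CPM, −1.37) and DDIT4 (−1.52). The unfolded protein response fell (4 of 18 down, 8 adjusted over the list alone; median −0.50, camera adjusted p = 6.08e-08, 0.0104 with an estimated correlation), with HERPUD1 (71.7 ± 4.09 to 30.5 ± 2.37 CPM, −1.24) and the chaperone HSPA5 (−0.98) down.

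Of 46 biogenesis factors 44 lay above 0 (median 0.40, camera adjusted p = 3.77e-06; adjusted p = 0.334 with an estimated correlation), with RRS1 called (0.93). Ribosomal protein mRNAs lay lower (median −0.19, camera adjusted p = 5.53e-06; adjusted p = 0.334 with an estimated correlation). RPL13A (77.8 ± 2.18 to 28.6 ± 5.25 CPM, log2 −1.44, edgeR adjusted p = 0.000134) and RPL3 (−1.21) were called, and both genes hold SNORD RNAs in their introns. Short-lived mRNAs (median 0.52, camera adjusted p = 0.000477; BTG2 0.99, GADD45A 0.70), decay targets (median 0.33, 0.000989; SRSF6 0.61) and decay machinery (median 0.22, 0.0339) lay higher, and cholesterol synthesis (median −0.19, 0.0148) and glycolysis (median −0.15, 0.0421; PFKL −0.40) lower. Those 5 were lost with an estimated correlation (adjusted p = 0.334, 0.193, 0.117, 0.193 and 0.377 with an estimated correlation, in that order). Of their named genes, SRSF6 lost its call in 22 of 30 alternatives, PFKL in 19, GADD45A in 18 and BTG2 in 12. edgeR called 0 of 68 G2/M and S phase genes in HEK293T with siFBL, against 4 higher and 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 (medians 0.03 and −0.11). Scaling to ribosomal protein mRNAs raised the median of all genes from 0.043 to 0.15, and these lists kept their direction under it, while that of the interferon list (−0.08) changed sign.

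NOP56 knockdown in HEK293T cells moved the p53 and stress lists in the same directions as FBL knockdown. NOP56 is the scaffold on which FBL sits, so its loss is another way to lower the particle. At 0 h, 28 genes changed, 18 up and 10 down. That count depends on the fit: it was 208 by DESeq2, 140 with a replicate block, 0 with the 0 h libraries alone (edgeR, 3201 at an unadjusted p under 0.05) and 0 to 33 without single libraries. RPL13A lost its call in 2 of 30 alternatives, HERPUD1 in 5, CYP27B1 in 9, and SNORD17 and NOP56 in 10. SHISA4 lost it in 14, ASNS in 15, NGRN in 16 and DDIT4 in 20. For AEN, SMTN and HSPA1B this held in 21, and for HILPDA and CEACAM19 in 23. The vitamin D hydroxylase CYP27B1 (1.33), CEACAM19 (1.27), SHISA4 (1.16), SMTN (0.90), the nuclease AEN (0.87, 120.9 ± 0.0493 CPM) and NGRN (0.87) rose most. Beside NOP56, the falls that the rule names were SNORD17 (log2 −1.47), DDIT4 (−1.43), the heat shock gene HSPA1B (−1.38), RPL13A (−1.24, edgeR adjusted p = 0.00289), HILPDA (−1.12), ASNS (−0.96) and HERPUD1 (−0.90).

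With siNOP56 the p53 list (1 of 28 up, 8 adjusted over the list alone; median 0.43, camera adjusted p = 1.07e-08, 0.00277 with an estimated correlation) rose. The integrated stress response (3 of 25 down, 6 adjusted over the list alone; median −0.13, camera adjusted p = 4.11e-05, 0.00383 with an estimated correlation) and the unfolded protein response (1 of 18 down, 4 adjusted over the list alone; median −0.36, camera adjusted p = 7e-08, 0.0107 with an estimated correlation) fell. Of 46 biogenesis factors 45 lay above 0 (median 0.42, camera adjusted p = 2.67e-09; adjusted p = 0.269 with an estimated correlation). Cholesterol synthesis, decay machinery, decay targets, C4-2 markers and fibroblast markers passed with the preset correlation and not otherwise (adjusted p = 0.115, 0.108, 0.222, 0.121 and 0.103 with an estimated correlation).

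Among the genes called with either siRNA in HEK293T, 12 rose with both and 8 fell with both, against 0.167 and 0.081 for independent lists. The same siCTRL libraries serve both contrasts. Across 14939 genes the correlation of the changes was 0.701, against a mean of 0.496 and a highest value of 0.516 in 20 simulations of unchanged groups with shared controls.

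Set directly against each other in HEK293T at 0 h, siFBL and siNOP56 differed in 3 genes: the targets FBL (−4.42) and NOP56 (2.08), and the receptor NOTCH3, which was lower with siFBL (28.2 ± 2 CPM) than with siNOP56 (61.5 ± 1.24; log2 −1.12, SE 0.133, edgeR adjusted p = 0.00119). The protease PCSK6 came next and was not called (0.59, edgeR adjusted p = 0.142). Ribosomal protein mRNAs lay lower with siFBL (median −0.17, camera adjusted p = 5.77e-06) and short-lived mRNAs higher (median 0.18, 0.00746), both lost with an estimated correlation (adjusted p = 0.708 with an estimated correlation for each). Scaling to ribosomal protein mRNAs raised the median of all genes from −0.004 to 0.122.

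The HEK293T time course puts the stability question to both knockdowns. With siCTRL, 17 of 42 short-lived mRNAs fell, with siFBL 29 and with siNOP56 22 (medians −0.06, −0.08 and −0.07 log2 per hour), and 23 of 33 G2/M mRNAs fell with each siRNA. The phosphatase DUSP5 fell at −0.21 per hour with siCTRL. In the main fit no gene had a called difference in slope between siFBL and siCTRL or between siNOP56 and siCTRL: edgeR called 0 of 14939 for each, against 449 and 197 at an unadjusted p under 0.05 and 6 and 3 by DESeq2. With a replicate block within each siRNA, edgeR called 2 for siFBL (963 at an unadjusted p under 0.05) and 0 for siNOP56. Hour as a factor gave 1 and 0. The smallest p-values were those of PLCG2 (0.10 per hour, edgeR adjusted p = 0.186) and RITA1 (0.04, edgeR adjusted p = 0.221) for siFBL, and C21orf62 (−0.23, edgeR adjusted p = 1) for siNOP56. Between siFBL and siNOP56, edgeR called C21orf62 (0.29 per hour, SE 0.047, edgeR adjusted p = 0.0342), a gene with few reads, and DESeq2 called 0, with 107 at an unadjusted p under 0.05 in edgeR. With the replicate number as a block, over all libraries or within each siRNA, edgeR called 0 (118 and 263 at an unadjusted p under 0.05). NOP56 mRNA fell from 356.6 ± 4.03 CPM at 0 h to 138.8 ± 0.99 at 24 h with siFBL and from 204.8 ± 1.34 to 162.9 ± 4.17 with siCTRL (slope difference −0.04 per hour, edgeR adjusted p = 1).

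By list, short-lived mRNAs had lower slopes with siFBL in HEK293T (median −0.02 per hour, 35 of 42 lower, camera adjusted p = 0.000343; adjusted p = 0.803 with an estimated correlation). These mRNAs also lay higher at 0 h with siFBL, and the slope uses the same 0 h libraries. A raised start and a faster loss therefore cannot be told apart for them. The box C/D core, 4 genes that include FBL and NOP56, also had lower slopes (median −0.02, camera adjusted p = 0.00165, 0.0279 with an estimated correlation; 2 lower adjusted over the list alone). The core also differed between siFBL and siNOP56 (median −0.02, camera adjusted p = 2.44e-07, 0.000416 with an estimated correlation). It holds the target of each siRNA, NOP56 at −0.0491 and FBL at −0.0235 per hour in this contrast. NOP58, which is no target, lay at −0.0245. The list test therefore cannot separate a change of the core from the knockdowns themselves. Biogenesis factors passed upward with either siRNA, and with siNOP56 S phase genes passed upward and short-lived mRNAs downward, all lost with an estimated correlation (adjusted p from 0.733 to 0.913 with an estimated correlation). RIP-enriched RNAs did not pass limma camera at 0.05 for slopes with siFBL or siNOP56, while the 500 with the highest RIP fold passed upward with siNOP56 with the fixed correlation and not with an estimated one (p = 0.34 with an estimated correlation). As differences from siCTRL at single hours, called genes rose with time, from 990 at 6 h to 2251 at 24 h with siFBL and from 102 to 794 with siNOP56.

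Comparing the lines asks whether FBL loss means the same thing in both. The cell cycle response of C4-2 cells was not seen in HEK293T cells. At 0 h the effect of siFBL differed between the lines for 1514 of 20558 genes, 578 higher and 936 lower in C4-2. FBL itself fell further in C4-2 by −2.03 (SE 0.668), which was not called (edgeR adjusted p = 0.0693) but became called in 21 of 37 alternatives.

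G2/M genes responded more negatively in C4-2 (30 of 33 called, 33 adjusted over the list alone; median difference −1.98, camera adjusted p = 4.7e-63, 0.00413 with an estimated correlation), and so did S phase genes (33 of 35; median −1.46, camera adjusted p = 9.9e-58, 0.000233 with an estimated correlation). CDC20 (−2.60), E2F8 (−2.59), PLK1 (−2.53), CKS1B (−2.08) and CDC45 (−2.05) were among them. MKI67, which fell in C4-2, stood at 524.5 ± 13.6 CPM with siCTRL and 473.4 ± 18.9 with siFBL in HEK293T. p53 targets responded more in C4-2 (11 of 27 called, 16 adjusted over the list alone; median 0.95, camera adjusted p = 2.87e-10, 0.0362 with an estimated correlation; CDKN1A 3.27, FAS 1.75), and so did interferon genes (5 of 37; median 0.70, camera adjusted p = 0.00302, 0.013 with an estimated correlation; IFIT1 2.87, IFI6 2.27). Decay machinery was lower in C4-2 (9 of 52 called, median −0.32, camera adjusted p = 2.58e-05, 0.0362 with an estimated correlation, CNOT3 −0.85, PATL1 −0.80), as was the box C/D core (2 of 4, camera adjusted p = 0.00238, 0.0223 with an estimated correlation, NOP56 −1.02, NOP58 −0.92). With a replicate block from the column names, decay machinery did not pass with an estimated correlation (camera adjusted p = 0.0591), while the core did (camera adjusted p = 0.0276).

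All 46 biogenesis factors lay lower in C4-2 relative to HEK293T, 12 of them called (20 adjusted over the list alone; median −0.61, camera adjusted p = 3.7e-13; TCOF1 −1.54, RRP12 −1.23), which did not pass with an estimated correlation (adjusted p = 0.0616 with an estimated correlation). Ribosomal protein mRNAs went the other way (median 0.19, camera adjusted p = 0.00238; adjusted p = 0.476 with an estimated correlation; RPL3 1.14, RPL13A 0.98). Decay targets lay lower (median −0.65, camera adjusted p = 4.56e-05; adjusted p = 0.0772 with an estimated correlation; SNHG1 −2.54). The stress genes DDIT4 (2.91), ASNS (1.15) and HSPA5 (0.90), which fell in HEK293T, and the largest rises SULF2 (4.48), CEL (4.43), ATP1B2 (4.19), ECEL1 (4.05), GSTP1 (3.95) and GPM6A (3.68) were higher in C4-2. GALNT3 (−4.06) and ZNF331 (−2.62) were the lowest. GSTP1 lost its call in 20 of 37 alternatives, CEL in 10, GALNT3 in 5 and GPM6A in 4. These lists kept their direction when scaled by DESeq2 size factors or to ribosomal protein mRNAs.

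**Figure D3:**
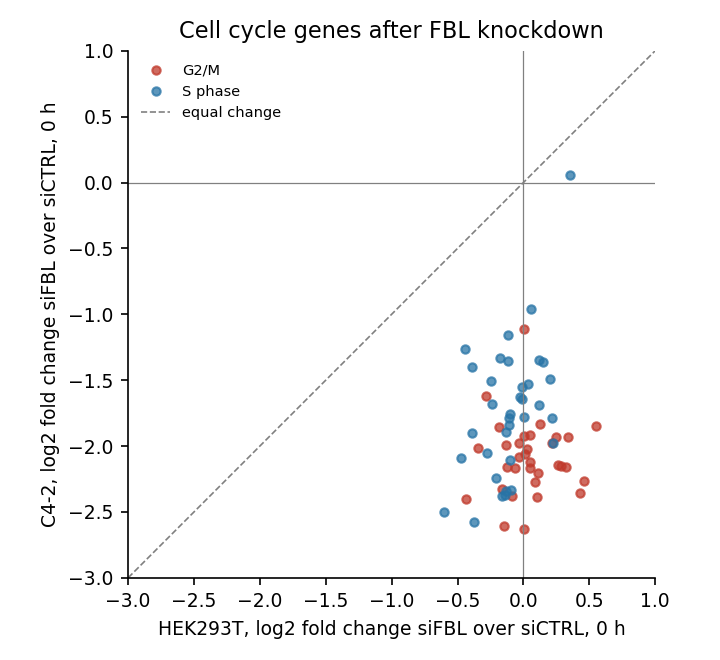
Change with siFBL at 0 h (log2 of siFBL over siCTRL) for each of 68 G2/M and S phase genes in C4-2 and HEK293T cells. The medians are −1.97 in C4-2 and −0.03 in HEK293T cells.

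SLAM-seq of C4-2 cells tracks labelled RNA through a chase, and its total reads give a further view of the steady state. Most cell cycle genes that fell in the C4-2 time course were not called here. With siFBL, total reads changed for 131 of 15344 genes, 48 up and 83 down, with the labelled hour in the model. With the hour of the file header in its place, chosen after seeing the data, edgeR called 1601 genes, 821 up and 780 down, the 131 among them. The siFBL libraries labelled 0 h and 12 h of replicate 2 stand apart (second principal component 56.7 and 57, the others from −19.8 to 7.3), and without them 75 of the 131 genes were called.

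FBL was called lower by edgeR (adjusted p = 0.0137), while DESeq2 gave it no adjusted p. TEX19 (1.51), the growth factor IGF2 (1.31), SLC10A7 (1.20), MAOA (0.998) and the retinal dehydrogenase ALDH1A3 (0.996) were among the genes that rose most. Of these, SLC10A7 lost its call in 16 of 26 alternatives, MAOA in 14, and IGF2 and ALDH1A3 in 13 each. The cohesin subunit SMC3 (−1.71), the kinetochore protein SKA2 (50.5 ± 8.29 CPM over 8 siCTRL libraries and 19.5 ± 4.55 over 8 siFBL libraries, −1.38), SDCBP (−1.34), ANAPC10 (−1.27) and MCFD2 (−1.23) were among those that fell most. C4-2 markers lay higher (2 of 20 up, 7 adjusted over the list alone, 9 with the header hour; median 0.43, camera adjusted p = 1.23e-06; TMPRSS2 0.61), as did cholesterol synthesis (3 of 21 up, 6 adjusted over the list alone; median 0.17, 2.43e-05; SREBF2 0.79). Ribosomal proteins lay lower (1 of 75 down, 26 with the header hour; median −0.22, 1.45e-09). Histones (median −0.43), snoRNA hosts (SNHG3 −0.77), the integrated stress response, short-lived mRNAs and leukocyte markers passed downward and p53 targets upward (median 0.17). SNHG3 lost its call in 18 of 26 alternatives. Of 27 p53 targets edgeR called 0 (2 higher and 0 lower at an unadjusted p under 0.05, 1 higher by DESeq2), and 6 higher with the header hour. With the header hour, histones, short-lived mRNAs and leukocyte markers did not pass (limma camera adjusted p = 0.0601 for histones, adjusted p = 0.0686 for short-lived mRNAs, adjusted p = 0.116 for leukocyte markers). A further list that passed with the labelled hour is not reported here. With an estimated correlation none of the lists that passed did so (adjusted p from 0.167 to 0.777 with an estimated correlation).

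edgeR called 0 of 68 G2/M and S phase genes in SLAM-seq, against 1 higher and 4 lower at an unadjusted p under 0.05 and 2, both lower, by DESeq2. With the header hour it called 4 of the 68 lower and 0 higher (median −0.05), against 6 lower and 1 higher at an unadjusted p under 0.05 and 5 lower and 1 higher by DESeq2. Scaling to ribosomal protein mRNAs raised the median of all genes from −0.018 to 0.154 and turned the G2/M (0.13 in place of −0.09), decay machinery, RNA methylation, snoRNP assembly, H/ACA core, HEK293T and fibroblast marker medians positive. RIP-enriched RNAs did not pass limma camera at 0.05 for total SLAM-seq reads (median 0.03).

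The T>C signal did not follow the labelled hours. A chase should lower the share of labelled reads with time. Neither replicate did so over the labelled hours. At labelled 0, 6, 12 and 24 h, reads with T>C conversions made up 56.9%, 22.9%, 56.8% and 23.1% in replicate 1 with siCTRL, and 53.9%, 19.6%, 53.6% and 20% with siFBL. In replicate 2 they made up 11%, 34.9%, 11.1% and 35.5% with siCTRL, and 5.14%, 31.1%, 5.32% and 31.4% with siFBL. By the hours in the file headers, conversions per sequenced T were 7.74% and 7.68% at 0 h, 4.02% and 3.92% at 6 h, 2.33% and 2.29% at 12 h, and 0.945% and 0.958% at 24 h with siCTRL. With siFBL they were 6.24% and 6.23%, 3.09% and 3.05%, 1.78% and 1.73%, and 0.258% and 0.268%. No loss of label over the chase was therefore tested between siRNAs.

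**Figure D4:**
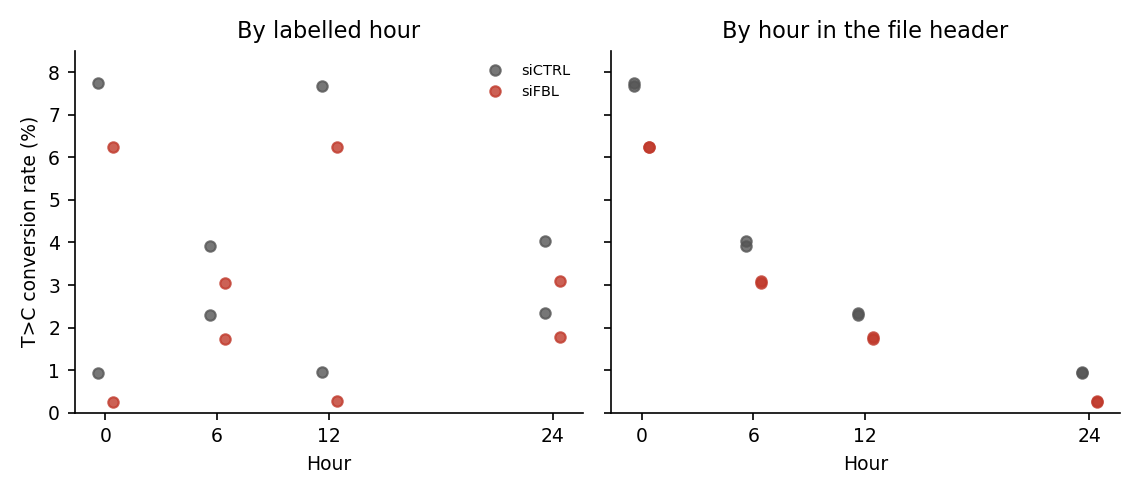
T>C conversions per sequenced T in % (vertical) of the 16 SLAM-seq libraries by labelled hour and by the hour in the file header (horizontal), for siCTRL and siFBL. With siCTRL the libraries labelled 0 h lie at 7.74% and 0.945%, while those with header hour 0 lie at 7.74% and 7.68%.

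In 4 libraries the label and the header give the same hour, 1 per siRNA at 0 h (replicate 1) and at 6 h (replicate 2). What follows describes those libraries, without a test between them. The percentiles rank lists among genes and do not measure the spread between libraries. Among 8367 genes with at least 100 reads in each, the median log2 ratio of the T>C share at 6 h over 0 h (pseudocount 0.01) was −1.20 with siCTRL and −1.25 with siFBL. Short-lived mRNAs lost label fastest (22 genes, −2.96 and −2.86, at percentile 0 of 10000 random lists matched on expression), and ribosomal protein mRNAs hardly (69 genes, −0.07 and −0.12, percentile 100). RIP-enriched RNAs lost more than average (1773 genes, −1.43 and −1.50, percentile 0). The random lists were not matched on transcript length, with which RIP enrichment rose. With 1 library per siRNA and hour, the siRNAs are not compared.

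Over all 16 SLAM-seq libraries, edgeR called 0 of 15344 genes for a change in the T>C share with siFBL, with 10 at an unadjusted p under 0.05; DESeq2 was not run for this share. NOP56 had an estimate of −1.69 (edgeR adjusted p = 1). The test, with the labelled hour as a term, recovered 0% of simulated changes, so that count says nothing about stability. A fit of the share with the hour of the file header was not run.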

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

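Of the tests below, those of scaling between libraries and of the extent of the knockdown were chosen after the result was seen; the test of sequencing depth and the counts of other splits were set before.

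The effect of siFBL at 0 h differed between C4-2 and HEK293T cells for 1514 genes by a test of the difference itself. Within it, 63 of 68 G2/M and S phase genes had a more negative response in C4-2 (median difference −1.77), such as CDC20 and PLK1. In C4-2, 67 of the 68 were called lower (median −1.97), while in HEK293T edgeR called 0 of 68 with siFBL, against 4 higher and 2 lower at an unadjusted p under 0.05 and 0 by DESeq2.

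For these cell cycle genes, a difference in sequencing depth as the cause is argued against: with the C4-2 libraries thinned from a mean of 95.3 to 17.7 M counts, 64 of 68 were called lower in the test of the difference. A difference in scaling is argued against as well, since the median difference was −1.72 with DESeq2 size factors and −1.84 with scaling to ribosomal protein mRNAs. The extent of the knockdown stays open: FBL fell further in C4-2 by −2.03 on the log2 scale, which was not called (edgeR adjusted p = 0.0693) but became called in 21 of 37 alternatives, and no dose series of the siRNA is among the groups. In SLAM-seq of C4-2 cells with siFBL, edgeR called 0 of the 68 genes (1 higher and 4 lower at an unadjusted p under 0.05, 2 lower by DESeq2, and 4 lower with the hour of the file header). The fall was thus not seen in each C4-2 experiment. The SLAM-seq libraries followed 4-thiouridine labelling and span a chase, unlike the time course at 0 h. The difference between these experiments was not tested. A biological difference between the lines, such as the T antigen in HEK293T, which binds p53 and RB proteins, may contribute but was not tested, and each line was also run as its own experiment, so line and experiment cannot be told apart.

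In C4-2 cells, 1 gene, PNRC2, had a called difference in slope between siFBL and siCTRL. Of 100 splits of the siRNA labels within hours, 3 called as many genes, the real split included. The highest of the other splits called 2906, which points to a structure of the samples; a split that exchanges the siRNAs at some hours only also turns the siRNA effect into a slope, and these were not separated. These splits do not exclude chance. Splits that mix the siRNAs add the siRNA effect to the spread within groups, which can lower their calls. The hours are not independent either, since within siFBL libraries A and B differ alike at each hour (median correlation over genes 0.759). The call ended in 20 of 24 alternatives, among them 14 of the 16 that leave out a single library.

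Between siFBL and siNOP56 in HEK293T, 3 genes differed at 0 h. Besides the targets FBL and NOP56 this was NOTCH3. With 2 libraries in each group there are too few splits for a share under 0.05, so none were counted.

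The slopes of siFBL and siNOP56 in HEK293T differed for 1 gene, C21orf62. Of 100 splits within hours, 4 called as many genes, the real one included, and the highest of the others called 1. Chance is not excluded by these splits, since those that mix the siRNAs add any siRNA effect to the spread, which can lower their calls. The hours are not independent either, since replicates differ alike at each hour within siFBL and siNOP56 (median correlations 0.867 and 0.783). With the replicate number as a block, over all libraries or within each siRNA, edgeR called 0 genes (118 and 263 at an unadjusted p under 0.05); DESeq2 was run without a block and called 0. The call rests on a gene with few reads (mean log2 CPM −1.69) and ended in 23 of 32 alternatives.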

How the results depend on the processing

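The replicate block within each siRNA, the block from the C4-2 column names, the distinct SLAM-seq intervals, the SLAM-seq fit without 2 libraries and the SLAM-seq fits with the hour of the file header were chosen after seeing the data. Named genes gave 6067 values under the alternatives: 5192 kept direction and side of the threshold, 826 lost the call, 42 gained one, 0 changed sign while called, and 7 uncalled values changed sign. For values that moved, the cause was not tested unless stated. The lone library left in a group by leaving out its partner is assumed to vary like the other groups.

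RIP counts stayed within 1.5 times (11800 to 12069 without each library; 12541 with the numbered pairs as a block), and a log2 limit of 1 left 7097 by construction.

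In C4-2 at 0 h the DESeq2 Wald test called 4015 genes in place of 1988, and scaling to ribosomal protein mRNAs called 940 up and 987 down, since it shifted the median gene by 0.219. Leaving out single libraries gave 633 to 3051: 633 without siCTRL 0 h A, 1245 without siCTRL 0 h B, 1100 without siFBL 0 h A, 1215 without siFBL 0 h B, 3051 without siFBL 12 h A and 3040 without siFBL 12 h B. The numbers in the C4-2 column names deviate together within siFBL (median correlation 0.759) and not within siCTRL (−0.082) or between the siRNAs (0.068), so they do not pair the libraries across the siRNAs; as a replicate block they gave 2670 at 0 h and 0 for the slope (3 with the block within siRNA), and 2183 for the comparison of lines. The slope call (PNRC2) became 0 with DESeq2 size factors, with no filter on low counts, with scaling to ribosomal protein mRNAs, with hour as a factor and without the last hour, and 24 by the DESeq2 Wald test. Without single libraries it was 0 to 10: 10 without siFBL 12 h A, and 0 without siCTRL 0, 3, 6 or 12 h A or B, siFBL 0 h A or B, 3 h A, or 6 h A or B.

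In HEK293T at 0 h, siFBL gave 778 genes by the DESeq2 Wald test, 861 with a replicate block, 172 with scaling to ribosomal protein mRNAs (67.4% up; median shift 0.107) and 1 with 0 h libraries alone, where fewer libraries estimate the spread. Without single libraries it gave 11 to 363: 11 without siCTRL 0 h replicate 1 or 2, 13 without siFBL 0 h replicate 2, 140 without siFBL 0 h replicate 1, 151 and 137 without siCTRL 6 h replicate 1 and 2, 164 without siCTRL 12 h replicate 1 or 2, and 153 and 152 without siCTRL 24 h replicate 1 and 2. siNOP56 gave 18 with DESeq2 size factors, 208 by the DESeq2 Wald test, 140 with a replicate block, 6 with scaling to ribosomal protein mRNAs and 0 with 0 h libraries alone (edgeR; 3201 at an unadjusted p under 0.05). Without single libraries it gave 0 to 33: 0 without siNOP56 0 h replicate 2; 1 without siCTRL 0 h replicate 1 or 2; 3 without siCTRL 6 h replicate 1 or siCTRL 24 h replicate 1 or 2; 5 without siCTRL 6 h replicate 2; 8 without siCTRL 12 h replicate 1 or 2; 9 and 14 without siFBL 6 h replicate 1 and 2; 10 without siNOP56 6 h replicate 2; 11 without siFBL 0 h replicate 1 or 2; 13 without siFBL 24 h replicate 1 or 2; and 14 without siNOP56 12 h replicate 1 or 2. siFBL against siNOP56 gave 19 by the DESeq2 Wald test and 2 to 5 without single libraries (5 without siNOP56 0 h replicate 1). Fits of all hours count the later libraries as independent, while replicates deviated alike at each hour within siFBL and siNOP56 (median correlations 0.867 and 0.783). Replicates of these groups also lay further apart than those of siCTRL. The p-values at 0 h can therefore be too small. Counts with 0 h libraries alone do not separate this from the loss of libraries.

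HEK293T slopes with siFBL gave 6 genes by the DESeq2 Wald test, 1 with hour as a factor, 2 with the block within siRNA, and 0 to 2 without single libraries (1 without siFBL 12 h replicate 2, 2 without siFBL 24 h replicate 1). With siNOP56 they gave 3 by the DESeq2 Wald test and 0 to 0 without single libraries. The slope difference (C21orf62) became 0 with no filter, by the DESeq2 Wald test, with either block, with hour as a factor and without the last hour, and was 0 to 1 without single libraries: 0 without siCTRL 0 h replicate 1 or 2, siCTRL 12 h replicate 1, siCTRL 24 h replicate 2, siFBL 6 h replicate 2, siNOP56 6 h replicate 1, siNOP56 12 h replicate 1, or any 0, 12 or 24 h siFBL or 0 or 24 h siNOP56 library.

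The comparison of lines gave 737 to 2350 without single libraries: 756 and 737 without HEK293T siCTRL 0 h replicate 1 and 2, 829 without HEK293T siFBL 0 h replicate 2, and 2350 and 2349 without C4-2 siFBL 6 h A and B. No filter on low counts shifted its median gene by −0.109.

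SLAM-seq totals gave 1601 with the hour of the file header (2380 by the DESeq2 Wald test), 596 with no filter, 616 by the DESeq2 Wald test and 614 with scaling to ribosomal protein mRNAs (569 up; median shift 0.17). Without single libraries they gave 68 to 119: with siCTRL 86, 80, 69, 79 and 73 without 0 h, 12 h, 24 h and 6 h replicate 1 and 6 h replicate 2, and with siFBL 81, 68, 78, 79 and 80 without 24 h and 6 h replicate 1 and 0 h, 12 h and 6 h replicate 2. Without the 2 siFBL libraries that stand apart, 75 of the 131 genes were among 109. The T>C share gave 0 to 1 (1 without siFBL 0 h or 12 h replicate 1).

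With an estimated correlation, lists that passed went from 6 to 0 in RIP, 17 to 4 in C4-2 at 0 h and 1 to 0 for its slope, 10 to 3 and 9 to 3 in HEK293T at 0 h for siFBL and siNOP56, 3 to 1 and 3 to 0 for their slopes, 2 to 0 between them at 0 h, 15 to 6 between lines and 10 to 0 in SLAM-seq. RIP-enriched RNAs at 0 h in C4-2 had p = 0.0972 with an estimated correlation; the 500 highest by RIP fold had higher slopes in C4-2 with siFBL (limma camera p = 0.00132; 0.228 with an estimated correlation) and in HEK293T with siNOP56 (limma camera p = 0.0369; 0.34 with an estimated correlation).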

Other observations

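The tests of the labelled hours, of library depth in SLAM-seq and of snoRNA host genes were chosen after the results were seen; the counts of other splits were set before.

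The T>C conversion rates of the SLAM-seq libraries do not follow the labelled hours. Mislabelled samples are a candidate explanation: libraries of 1 siRNA that share a labelled hour differ by up to 24.2 times (at least 1.71 times), while those that share the hour in the file header differ by at most 1.04 times. A difference in depth is argued against, because the 5 pairs with the same header hour and more than 1.5 times different mapped reads (up to 2.54 times) differ by at most 1.03 times in conversion rate. In replicate 2, reads with T>C conversions rose from labelled 0 h to 24 h, from 10.98% to 35.46% with siCTRL and from 5.14% to 31.35% with siFBL. A chase should lower this share, so these values argue against the labelled hours as chase times. By header hour the conversion rates fell from each hour to the next with both siRNAs. The header hours were not checked against another record, and no biological explanation was tested.

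Genes that host box C/D snoRNAs in their introns were examined because RPL13A and RPL3 fell in HEK293T cells with siFBL, and because loss of the snoRNP could lower its hosts. As a class they did not fall: the median of 58 box C/D hosts was 0.03 with siFBL, at percentile 17.3 of 10000 random lists matched on expression, and 0.05 with siNOP56, at percentile 12.1. H/ACA hosts lay at percentiles 21.1 and 23.8, and box C/D hosts without ribosomal proteins at 92.5 and 72.5. In C4-2 cells with siFBL, 58 of 62 box C/D hosts lay below 0 (median −0.42, percentile 0.02; 0 without ribosomal proteins), with H/ACA hosts at percentile 2.63, and these are 9 list tests in all. Among ribosomal protein mRNAs, with RPL13A and RPL3 left out because they prompted the test, the 14 box C/D hosts lay lower than the 61 others in HEK293T with siFBL (means −0.336 and −0.141, permutation p = 6e-04, adjusted over 3 tests 0.0018), which argues against a fall of the class as the whole cause, though the others lay below 0 as well; with siNOP56 (−0.06, permutation p = 0.229) and in C4-2 (−0.09, permutation p = 0.366) they did not differ beyond chance, and genes are not independent replicates, so this is a hypothesis about those hosts.

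Counts of other splits of the siRNA labels within hours bear on the remaining comparisons of at least 3 samples per group. Where the real count was 0, each split calls at least as many by construction, so the splits decide nothing: this holds for siFBL slopes in HEK293T (100 of 100 splits, the highest calling 1758), for siNOP56 slopes (100 of 100, the highest 146) and for the T>C share (21 of 21, the highest 9). Those highest counts of the slopes point to a structure of the samples, which can be the siRNA effect itself where a split exchanges siRNAs at some hours only. For SLAM-seq totals, 2 of 100 splits called at least the real 131 genes, the real one included, and the highest other called 1029, which also points to a structure. Chance is not excluded there, since splits that mix the siRNAs add the siRNA effect to the spread, which can lower their calls. Libraries that share a header hour also lie close together (with siCTRL, first principal component −41.9 and −41.4 at header hour 0, and 45.9 and 44.8 at 24).

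In HEK293T the deviations of replicate 2 from replicate 1 were shared between hours within siFBL (median correlation over genes 0.867) and within siNOP56 (0.783), and not within siCTRL (0.056) or between siFBL and siNOP56 (0.017). The squared differences between replicates, relative to counting noise, were 1.5 to 84.1 in HEK293T, 11.6 to 163.6 in C4-2, 3.77 to 9.28 in RIP and 25.1 to 268.7 in SLAM-seq, where the 2 libraries of a labelled hour carry different header hours, so that range can reflect the hour as well as the spread of replicates. MCFD2 in HEK293T at 0 h with siFBL shows that spread, at 77.1 ± 52.7 CPM (n = 2) against 115.6 ± 2.53 with siCTRL. In SLAM-seq the siFBL libraries labelled 0 h and 12 h of replicate 2, which share header hour 24, held NOP56 at 57.3 and 58.1 CPM, against 14.4 and 14.8 in the siCTRL libraries with that header hour.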
